A study of Drosophila simulans and Drosophila sechellia and Drosophila simulans x Drosophila sechellia with 72 samples.

How the data were processed

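The values used here are FPKM as deposited by the authors in 1 table of 7836 genes and 96 columns, 48 for libraries of the parental species and 48 for the 2 alleles of 24 hybrid libraries. Per the submitters' processing notes, read quality was checked with FastQC, reads were aligned with Bowtie2 and FPKM were computed with Cufflinks. Tool versions, the genome builds and the assignment of hybrid reads to alleles are not given in the sources used here. Each library pooled RNA of 10 entire animals, adult females or third-instar larvae described as female, kept at 20 °C with 16 h of light and 8 h of dark. Poly(A) RNA was sequenced on an Illumina instrument. Raw reads were not used here, and read depth cannot be recovered from FPKM. The smallest value above 0 ranged from 0.00399 to 0.0134 in D. simulans larvae and from 0.257 to 0.877 in the D. sechellia allele columns of hybrid adults, so the floor differs between columns. Every column is 0 for 15 genes, and 3888 are named by a CG number.

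A hybrid library's expression is the sum of its 2 allele columns. Genes with at least 1 FPKM in at least 3 libraries of a fit were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with moderated variances that follow a mean-variance trend. All p in the text come from limma unless another test is named. Adult and larval libraries were fitted separately, 36 each, with 1 mean for each of the 12 groups, and contrasts gave the effect of species, current medium, previous medium, their interactions, and hybrids against the mean of the parents. That mean is of log2 values. Where the parents differ it lies below the log2 of their mean FPKM, so hybrids midway in FPKM count as higher. Stage was tested in the 48 parental libraries. For alleles, each column was scaled to a total of 1000000 (scaled FPKM), and the allelic ratio was tested within hybrid libraries with the library as a block. The difference between the parental and the allelic ratio was tested in 1 fit of parental and allele columns. A call is a Benjamini-Hochberg adjusted p under 0.05, adjusted over the genes of 1 contrast. Each media effect was also fitted with the libraries of its genotype alone.

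Gene groups were 27 lists of families, pathways and tissue markers, tested with camera at a preset correlation of 0.01 where at least 5 members were tested. Adjusted p over the lists are also given with an estimated correlation, and fry was run as an alternative. The calls that held with an estimated correlation number 5 over all contrasts.

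The design, the lists, the contrasts, the alternatives other than those named below and the rule for names were fixed before the data were examined. The rule names, per contrast, up to 5 called genes in each direction with the largest log2 difference, a mean of at least 5 FPKM and a name other than a CG number, up to 4 genes of smallest p from each list that was called or had 3 or more called members, the noni candidates, and up to 5 interactions. Variance shares are the sums of squares of the main effects and interactions of the balanced design, summed over genes with at least 1 FPKM in 3 libraries, as a percentage of the total.

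The pipeline was tested on simulated data drawn with each gene's mean and residual SD in these libraries, or their shuffled residuals for alleles, with 200 changed genes. Of 2-fold changes between the species 86% were called in adults and 74% in larvae, and of 4-fold changes 97% and 94%. For the current medium, 2-fold changes were called in 64% (D. simulans), 71% (D. sechellia) and 70% (hybrids) of adult genes, and in 41%, 37% and 50% of larval genes. For allelic ratios 39% of 2-fold and 75% of 4-fold changes were called in adults, and 9% and 67% in larvae. False calls for the current medium in hybrids numbered 248 in adults and 197 in larvae, and 7 and 3 with hybrid libraries alone. That last fit called fewer true changes, 29% of 2-fold and 67% of 4-fold ones in adults and 10% and 50% in larvae.

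Alternatives were median-ratio rescaling (factors from genes above 0 in every library of a stage, 4664 in adults and 4545 in larvae), no filter on low values, a pseudocount of 0.1, limma without the trend, the replicate number as a block, only the libraries compared, a total shared by both allele columns, the library block left out, and each library left out in turn. Weights per genotype, restricted sets of genes, unscaled allele columns and median-ratio rescaling for the variance shares were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.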

Results

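The series asks how life stage, genotype and the media of the present and previous generation rank as sources of expression differences, and how much of the divergence between 2 fly species lies in cis and in trans. RNA was sequenced from 72 libraries of Drosophila simulans, Drosophila sechellia and their hybrids, 36 from adults and 36 from larvae, each of 10 whole animals described as female. Octanoic acid is the main toxic compound of noni fruit, the host of D. sechellia. Groups are written as previous then current medium, with S for standard medium and O for medium with octanoic acid, so that OS flies had parents on octanoic acid and were themselves on standard medium. Each of the 24 groups had 3 biological replicates. The table gives gene symbols without coordinates, and 0 of its 7836 names matched the reference gene table, so no positions are given. Values are FPKM, and changes are log2 differences of FPKM + 1.

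Life stage came first among the sources of variance. Stage accounted for 47.1% of the summed squares over 7490 genes and genotype for 30.1%. Their interaction took 5.64%. The current medium accounted for 0.283% and the previous medium for 0.29%, interactions that involve a medium for 4.08%, and differences between replicates for 12.4%. Leaving out each replicate number in turn gave SDs of 1.22 percentage points for stage, 0.566 for genotype, 0.044 for the current and 0.13 for the previous medium. These SDs do not cover the shares of the full data, since each such fit put the current medium higher, at 0.373% to 0.461%, and the previous medium at 0.313% to 0.556%. The order of the 2 media terms is left open. Both were below the share between replicates, but shares were not divided by degrees of freedom. Replicates hold far more of these than a media term, and media interactions more than a main effect. Noise alone gives every term some share, and the share without any effect was not computed. No ranking of media terms, their interactions and replicates is thus read from these shares. With a pseudocount of 0.1 the genotype share was 25.3% and the stage share 49.3%. The genotype share includes hybrid totals, for which the assignment of reads to alleles is not stated. It also includes parental columns whose summed FPKM differ in scale between the species. Part of that share may thus come from processing, and it is not read as differences in transcript alone.

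**Figure D1:**
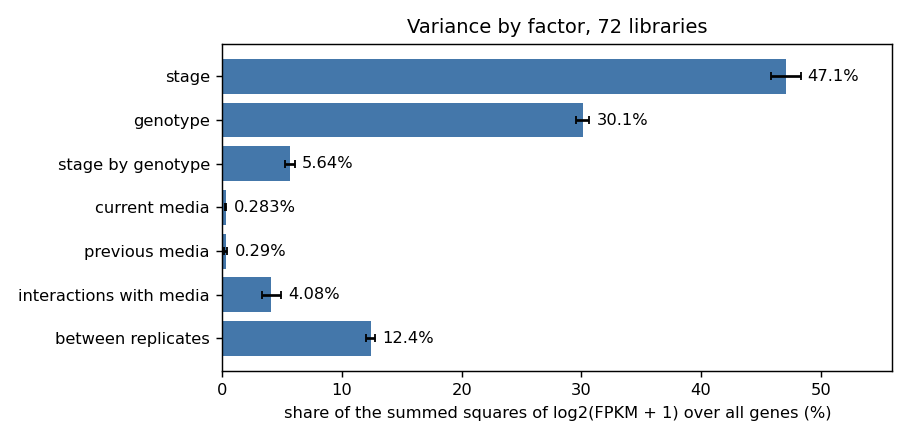
Share of the summed squares of log2(FPKM + 1) over 7490 genes (percent, x axis) taken by each factor (y axis) in 72 libraries. Bars are the shares, error bars the SD over the 3 fits that leave out 1 replicate number each, and stage (47.1%) and genotype (30.1%) exceed both media terms (0.283% and 0.29%).

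Adults of both parental species carried far more transcript of egg, flight-muscle and eye genes than larvae. Yp1, a yolk protein gene, stood at 8072 ± 3998 FPKM in adults and 0.743 ± 3.38 in larvae (SD, n = 24 each; log2 difference 12.57, adjusted p = 3.55e-38). The flight-muscle genes TpnC4 (11.11) and fln (10.74) and the eggshell gene Vm26Aa (11.55) were higher in adults by similar amounts. Larval cuticle genes went the other way, with Lcp4 at -12.00 and Lcp1 at -11.72, and Cpr78E fell from 4553 ± 2139 FPKM in larvae to 49.8 ± 56.7 in adults. The ecdysone-inducible gene ImpE2 was also lower in adults (-8.10). Of the list of egg and ovary genes, 17 of 17 were higher in adults, as were 10 of 12 genes of neurons and eyes, among them trp (6.46) and Arr1 (7.24), which act in phototransduction. All 8 lipid synthesis genes were higher, including ACC (3.27) and FASN1 (3.90), and so were 20 of 23 genes of mitochondrial complex I, such as ND-51 (2.39), and 8 of 11 muscle genes, with 2 lower. All 23 proteasome genes were lower in adults. Some are testis-specific subunits, such as Prosalpha3T with -4.02 (18.3 ± 9.99 FPKM in larvae, listed at 0 in 21 of 24 adult libraries). Of 62 cuticle protein genes 40 were lower and 16 higher. In the list of testis and accessory gland genes 6 of 7 were lower in adults: the sperm gene dj stood at 70.1 ± 40.1 FPKM in larvae and between 0 and 0.41 in adults, and Mst98Cb at 52.6 ± 26.4 in larvae and between 0 and 0.209 in adults. The larval libraries are described as female.

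In all, 6287 of 7361 tested genes differed between the stages, 3342 higher and 2945 lower in adults. Median-ratio rescaling moved the median of all genes from 0.09 to -0.15 and gave 6327 genes, 2727 higher and 3600 lower. Under it the 8 lists named above kept their direction, while ribosomal protein genes went from 13 higher and 13 lower to 2 higher and 40 lower, and P450 genes from 22 higher and 14 lower to 17 and 18. The camera calls of these 8 lists had adjusted p from 8.26e-08 for egg and ovary genes to 0.0354 for muscle genes. All were lost with an estimated correlation, where adjusted p = 0.533 to 0.697 with an estimated correlation. The list counts were the same adjusted over the list alone.

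In adults the digestive proteases Jon99Cii, epsilonTry and Jon44E were lower in D. sechellia. At the deposited scale more genes of the digestive list were higher than lower. Most antimicrobial peptide, P450 and glutathione transferase genes were also higher at that scale, as were most genes of any kind. Fad2, a desaturase in the synthesis of female cuticular hydrocarbons, stood at 1388 ± 378 FPKM in D. sechellia and 0.996 ± 0.202 in D. simulans (n = 12 each; 9.39, adjusted p = 1.87e-26). The serine proteases Jon99Cii (9.9 ± 5.92 against 600.0 ± 77.2 FPKM; -5.98), epsilonTry (-6.81) and Jon44E (-6.21) were lower, and the trypsin lambdaTry was higher (3.42). Of 20 antimicrobial peptide genes 17 were higher and 1 lower, led by AttC (5.85), the immune-induced peptide IM2 (6505 ± 2193 against 228.2 ± 370 FPKM; 5.39) and IM4 (3.98). With median-ratio rescaling 13 were higher and 1 lower. Of 43 P450 genes 36 were higher and 3 lower (25 and 8 rescaled), with Cyp12d1-d at 4.72 and Cyp9b1 at 4.69. Of 14 glutathione transferase genes 12 were higher and 2 lower (7 and 2 rescaled), with GstE2 at 5.03, GstE3 at 4.60 and GstE1 at -1.53. Antioxidant genes such as Prx5 (2.13) and Cat (2.11) were among 10 of 11 higher members of the oxidative stress list, with 1 lower adjusted over the list alone and 6 higher and 1 lower rescaled. The gut lipase gene mag was lower (5.61 ± 1.77 against 141.5 ± 19.7 FPKM; -4.47) and the lipase gene CG5966 higher (2.05). Some genes were listed at 0 in 1 species: UQCR-14, a complex III subunit, at 2723 to 6127 FPKM in D. sechellia libraries and at 0 in all 12 of D. simulans, and Cdlc2 and Tfb5 at 0 in 11 of 12. RpS28a and OSCP1 had the reverse (3.76 ± 1.615 against 5578 ± 626, and 1.69 ± 0.722 against 1093 ± 85.1 FPKM). The adult values listed 107 genes at 0 in all D. simulans libraries with a D. sechellia mean of at least 5, and 3 genes the other way. Every cell uses UQCR-14, the transcription factor gene Tfb5 and ribosomal proteins, so such values are not read as differences in transcript, and a gene missed by annotation or mapping in 1 genome is not excluded. Nor is it excluded for Jon44E, Jon99Cii and epsilonTry, whose D. sechellia allele was listed at 0 in 12, 10 and 8 of 12 hybrid adult libraries.

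The counts between the adult species depend on the scale. Summed FPKM ran from 483241 to 515024 in D. simulans and from 1090157 to 1454241 in D. sechellia. The median of all 6420 tested genes was 0.72, and 4632 genes differed, 4316 higher and 316 lower in D. sechellia. Median-ratio rescaling, which divides D. simulans values by a mean of 0.626 and D. sechellia values by 1.09, gave 3651 genes, 2029 higher and 1622 lower, with a median of 0.07. Relative to the median of all genes, lipid synthesis genes lay at 0.91 (8 of 8 higher, 7 of 8 rescaled) and complex I genes at 0.52 (20 of 20, 14 of 20 rescaled). Their camera call, adjusted p = 0.000461 for both, was lost: adjusted p = 0.481 with an estimated correlation. Ribosomal protein genes, at the same 2 p, lay at 0.02. Their 48 higher and 2 lower members, 3 lower adjusted over the list alone, became 13 and 13 rescaled, and their median of 0.75 flipped to -0.02. Fatty acid oxidation (19 higher and 1 lower of 21, camera adjusted p = 0.0214) and oxidative stress genes (0.0462) were called higher, and adjusted p = 0.481 with an estimated correlation for both. Rescaled, 8 fatty acid oxidation genes were higher and 5 lower, with a median of 0.08. For egg and ovary genes (7 higher, 7 lower, median 0.18, mean -0.30), lipases (5 higher, 3 lower, median 0.23, mean -0.29) and digestive enzymes (9 higher, 4 lower, median 0.73, mean -0.20) camera called the list lower than other genes. Their adjusted p of 0.00236, 0.00433 and 0.0462 became adjusted p = 0.481, 0.231 and 0.481 with an estimated correlation. The medians of these 3 lists flipped when rescaled, to -0.61, -0.36 and -0.07. Antimicrobial peptide genes did not pass camera (adjusted p = 0.242), nor did P450 (0.0519) or glutathione transferase genes (0.478).

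In larvae most antimicrobial peptide genes were higher in D. sechellia, and DptA was lower. Def, a defensin, stood at 1198 ± 531 FPKM in D. sechellia and 2.24 ± 1.54 in D. simulans (n = 12 each; 8.49, adjusted p = 7.61e-16), and IM4 (6.39) and CecA2 (7.70) were higher as well. DptA, a diptericin, stood in D. sechellia at 14.7 ± 8.16 against 936.1 ± 486 FPKM (-5.95, adjusted p = 4.96e-21). Of 22 antimicrobial peptide genes 18 were higher and 1 lower, 19 and 2 adjusted over the list alone, and 15 and 2 with median-ratio rescaling; camera gave an adjusted p of 0.0524. The proteases Jon44E (-7.71), epsilonTry (-7.37), gammaTry (-7.29) and Jon65Aii (-6.23) were lower, with the limit on mapping given for such genes in adults. The amylase genes Amy-p (6.51) and Amy-d (5.98) were higher, and their D. simulans values were identical in mean and SD (2.75 ± 2.29 FPKM), so the 2 copies are not resolved there. Of 16 digestive genes 6 were higher and 6 lower, and 8 higher and 6 lower adjusted over the list alone (median 0.06, flipped to -0.50 rescaled, mean -0.83). Camera called them lower than other genes (adjusted p = 0.0143), and adjusted p = 0.708 with an estimated correlation. GstE3 was higher by 6.72. The complex III gene ox was listed at 1194 to 1714 FPKM in D. sechellia libraries and at 0 in all 12 of D. simulans. Every cell uses it, so this is not read as a difference in transcript, as for UQCR-14 in adults. GNBP-like3 had 1580 ± 699 against 0.663 ± 0.6755 FPKM. RpS28a (-10.19) and OSCP1 (-9.73) were lower, as in adults.

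In larvae 3998 of 7167 genes differed between the species, 3542 higher and 456 lower in D. sechellia, with a median of 0.56. Rescaled, 3713 differed, 2038 higher and 1675 lower, with a median of 0.04. Ribosomal protein genes lay 0.87 above the median of all genes (48 of 52 higher, 49 adjusted over the list alone, 44 rescaled; camera adjusted p = 1.78e-11), and complex I genes 0.60 above it (20 of 23 higher, 21 adjusted over the list alone, 14 rescaled; 0.00463). Cuticle genes had 19 higher and 6 lower members, 18 and 4 adjusted over the list alone, and a median of 0.52. The counts flipped to 10 higher and 14 lower rescaled, and camera called them lower than other genes (0.0401). All 3 calls were lost, with adjusted p = 0.708 with an estimated correlation. Among genes linked to noni adaptation, Catsup (0.86 in adults, 1.17 in larvae), ple, which encodes tyrosine hydroxylase (0.83 and 2.42), and the olfactory receptor gene Or22a (1.42, tested in adults) were higher in D. sechellia. For ple in larvae the means were 1424 ± 786 FPKM and, in D. simulans, 637.8 ± 637.5 with a range of 5.01 to 2128. Its larval difference thus contains the shift of D. simulans larvae with the previous medium described below, whose calls single libraries decide. Cyp4d8 was lower in adults (-1.06) and higher in larvae (1.66). In adults Catsup (0.08) and ple (0.07) were no longer called when rescaled, and ple lost its call without D. sechellia SO replicate 2, SO replicate 3 or OS replicate 1 (adjusted p = 0.0523, 0.0533 and 0.0598). At the deposited scale Est-6 had 0.20 in adults and was called in neither stage, nor were Osi8 (-0.54, adults) and Osi6 in larvae. Rescaled, 1 of the 6 noni candidates tested in adults was higher and 3 were lower. As Catsup and ple were not called then, Est-6 and Osi8 were.

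**Figure D2:**
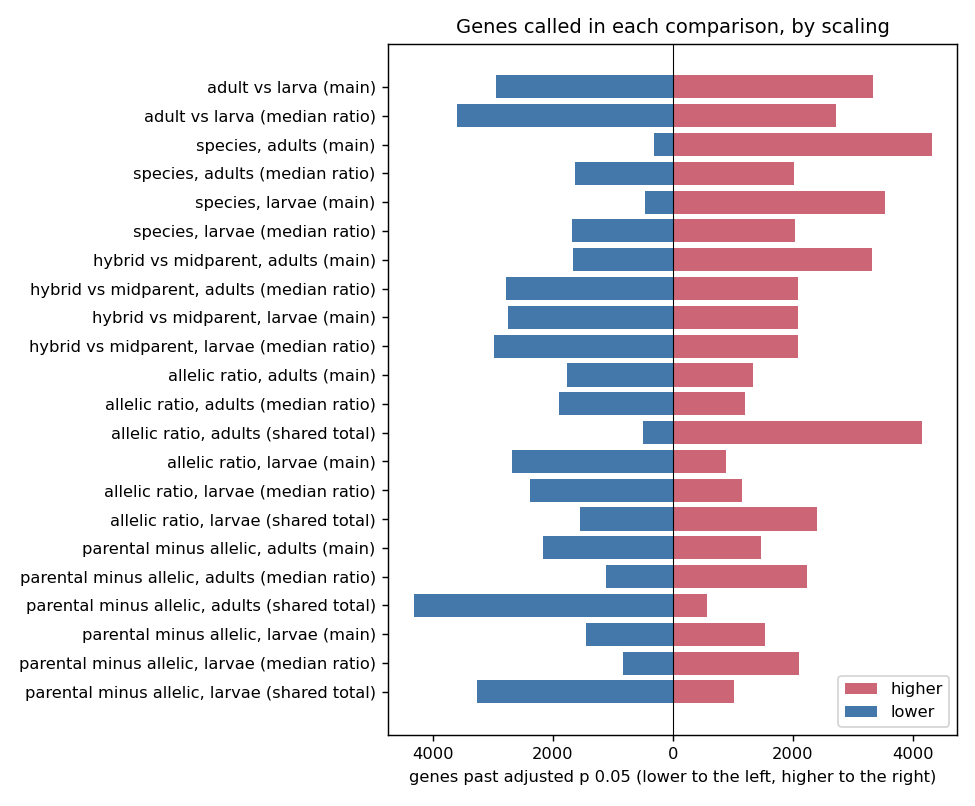
Number of genes past an adjusted p of 0.05 (x axis; lower to the left, higher to the right) for each comparison (y axis) under the main scaling, median-ratio rescaling and, for alleles, a total shared by both allele columns. The adult species comparison goes from 4316 higher and 316 lower genes to 2029 and 1622 with median-ratio rescaling.

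Current medium changed few genes in the parental species. In D. simulans adults limma called 0 of 6420 genes for octanoic acid against standard medium, with 15 at an unadjusted p under 0.05, and 0 with its own libraries alone (116 unadjusted). In D. sechellia larvae it called 0 of 7167, with 26 unadjusted, and 0 with its own libraries alone (109 unadjusted). Each of these unadjusted counts was below the number expected at that threshold without any effect. Genes outside the rule for names are given here and below because their count is at most 5, and they were chosen after their values were seen. CG34312 was the 1 call in D. sechellia adults (-1.14, adjusted p = 3.38e-06): it was listed between 4.53 and 4.99 FPKM in the 3 OS libraries and at 0 in 8 of the other 9. With D. sechellia libraries alone it was not called (adjusted p = 0.149). Wdr24 was the 1 call in D. simulans larvae (1.40, adjusted p = 0.00636): it was listed at 0 in the 3 OS libraries and at 4.3 to 6.63 FPKM in the other 9, and it was called with D. simulans libraries alone (adjusted p = 0.00314). Cuticle protein genes lay at a median of -0.31 in D. sechellia larvae on octanoic acid, with 0 of 58 past the test singly and camera adjusted p = 1.05e-16, and adjusted p = 0.0494 with an estimated correlation. Muscle genes (-0.33; 0.000541) and lipases (-0.28; 0.00838) went with them, and adjusted p = 0.29 and 0.487 with an estimated correlation. On the first component of the differences between replicates of these larvae the 3 lists lie together, at median ranks of 92.7%, 97.0% and 97.5%, so spread of that kind between libraries is not excluded as their source. In D. simulans adults cuticle genes had a median of -0.21 (2.14e-08) and adjusted p = 0.388 with an estimated correlation, and fry gave an adjusted p of 0.998. Egg and ovary genes had a median of 0.55 in D. sechellia adults (0 of 17 past the test; 1.9e-09), and adjusted p = 0.572 with an estimated correlation. None of the noni candidates tested, 6 in adults and 5 in larvae, passed in any genotype, also adjusted over the list alone. For ple the difference was 1.80 in D. simulans larvae and 0.11 in D. sechellia larvae, adjusted p = 1.0 in limma for both.

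Some of these counts rest on single libraries. The D. sechellia adult count was 0 without OS replicate 1 or 3, 4 without OS replicate 2 and 2 without SS replicate 1, SO replicate 1 or OO replicate 3. For D. simulans larvae it was 3 without SO replicate 2 and 2 without SS replicate 1, SS replicate 3, SO replicate 3 or OO replicate 1. D. simulans adults had 1 call without SO replicate 2, and D. sechellia larvae 1 without SS replicate 2. Simulated libraries without any change gave 7 false calls for the current medium in D. sechellia adults in the fit of all genotypes. D. simulans larvae had 1 and D. sechellia larvae 1, and with the libraries of each genotype alone all had 0. CG34312 and Wdr24 are thus within what the fit of all genotypes gave without an effect, though Wdr24 also passed with its own libraries. In simulated data built from these libraries, the fit of all genotypes called 64% of 2-fold and 90% of 4-fold changes in D. simulans adults. For D. sechellia larvae it called 37% and 82%. That fit also takes its variance from hybrids, whose replicates spread more. With the libraries of the genotype alone the shares were 95% and 99% in D. simulans adults and 69% and 94% in D. sechellia larvae. False calls were then more, 16 against 7 and 9 against 2. In the real data this second fit called 0 genes in both sets, so these null counts do not rest on the weaker fit alone.

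Hybrids had more calls for the current medium, and few held with the spread of the hybrids alone. In hybrid adults 432 genes passed, 127 higher and 305 lower. Smyd5, a lysine methyltransferase gene, stood at 21.2 ± 6.71 FPKM on octanoic acid and 5.06 ± 5.6 on standard medium (n = 6 each; 2.28, adjusted p = 7.59e-07), and the vesicle fusion gene Ykt6 at 7.15 ± 7.27 and 34.96 ± 17.9 (-2.28, 0.000281). In hybrid larvae 68 passed, led by Apf, a nucleotide hydrolase gene, at 6.02 ± 7.76 and 47.4 ± 27.7 FPKM (-3.45, adjusted p = 0.000131). Replicates of hybrids spread more than those of the parents, with a median residual SD of 0.60 in adults (0.16 in D. simulans, 0.37 in D. sechellia) and 0.78 in larvae (0.39 and 0.34). With hybrid libraries alone 0 adult and 3 larval genes passed, with 660 and 298 unadjusted, and Smyd5, Ykt6 and Apf had adjusted p = 0.385, 0.385 and 0.306. That fit called only 29% of simulated 2-fold changes in adults and 10% in larvae, so a call lost there does not show that an effect is absent. Simulated hybrids without any change gave 175 false calls in adults and 165 in larvae in the fit of all genotypes. The adult count rose to 690 without OO replicate 1. The larval count was 464 without SO replicate 2, 154 without OS replicate 3, 122 without OO replicate 1, 117 without SS replicate 3 and 104 without SO replicate 1.

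Previous medium: 2 genes of digestive proteases fell in D. sechellia adults whose parents had been on octanoic acid. Jon99Cii, a Jonah serine protease gene, stood at 4.83 ± 1.29 FPKM after octanoic acid and 14.97 ± 3.71 after standard medium (n = 6 each; -1.45, adjusted p = 9.11e-06), with 3.28 to 6.34 against 9.28 to 19.4 per library. The trypsin gene epsilonTry had 11.1 ± 2.66 and 27.1 ± 8.63 FPKM (-1.19, adjusted p = 0.00821), and CG2233 had 2.95 ± 1.71 and 7.04 ± 0.839 (-1.15, adjusted p = 0.0337). The other 2 of the 5 calls rose: CG1690 (1.86, adjusted p = 0.00869) and CG34312 (1.14, adjusted p = 3.38e-06). Jon99Cii and epsilonTry were 2 of 16 digestive genes, also adjusted over the list alone, and the list (median 0.08, mean -0.12) did not pass camera (adjusted p = 0.118). Egg and ovary genes lay at a median of -0.70 with 0 of 17 past the test (camera adjusted p = 1.45e-14), cuticle genes at 0.34 with 0 of 47, or 1 adjusted over the list alone (4.71e-09), and neuron and eye genes at 0.31 with 0 of 12 (1.5e-07). Each had adjusted p = 0.115 with an estimated correlation. Single libraries carry part of this: the egg and ovary genes of OS replicate 1 lay at a median of -2.75 from their mean over the 12 libraries, and without it the median difference was -0.25. For cuticle genes it was 0.13 without SO replicate 1, and for neuron and eye genes 0.20 without OS replicate 1. With D. sechellia libraries alone 0 genes passed (96 unadjusted), and Jon99Cii had an adjusted p of 0.0745 and epsilonTry 0.836. In simulated D. sechellia adults without any change the fit of all genotypes gave 7 false calls for the current medium, more than the 5 here. No such count was made for the previous medium. The count was 24 without OS replicate 2 and 3 without OS replicate 1, where CG1690 had an adjusted p of 0.0635. CG2233 lost its call without any 1 of 7 libraries: SS replicates 1 to 3, SO replicates 1 and 2, OS replicate 3 and OO replicate 3, with adjusted p from 0.0595 to 0.142.

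In D. simulans adults limma called 0 genes for the previous medium (21 unadjusted; 0 with its own libraries, 159 unadjusted), and 1 without OS replicate 1 or OO replicate 1. Antimicrobial peptide genes had a median of 0.21 there, with 0 of 20 past the test (camera adjusted p = 3.63e-10), and adjusted p = 0.0899 with an estimated correlation. With fry their adjusted p was 0.966. In hybrid adults 109 genes passed, among them AnxB11, an annexin gene (4.34 ± 3.89 FPKM after octanoic acid, 14.97 ± 6.31 after standard medium, n = 6 each; -1.82, adjusted p = 0.00288), and Gadd45, a stress-response gene (94.1 ± 35.8 and 36.2 ± 32.5; 2.00, adjusted p = 0.0164). With hybrid libraries alone 0 passed (248 unadjusted) and both had an adjusted p of 0.998. The hybrid count was 169, 177 and 205 without SO replicates 1, 2 and 3, 174 without OS replicate 2, 192 without OO replicate 1 and 179 without OO replicate 2 or 3.

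**Figure D3:**
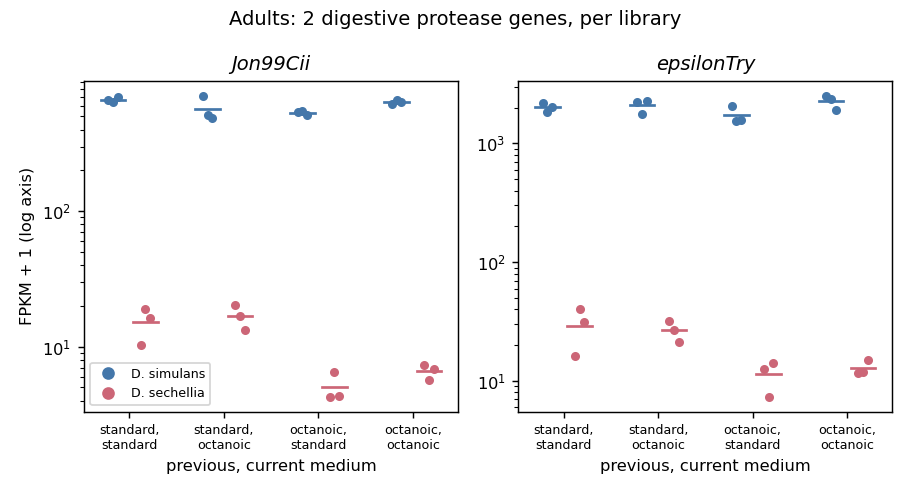
FPKM + 1 (y axis, log scale) of Jon99Cii and epsilonTry in each adult library of both species, by previous and current medium (x axis). Points are libraries and bars are means of 3; D. sechellia libraries after octanoic acid lie at 3.28 to 6.34 FPKM for Jon99Cii against 9.28 to 19.4 after standard medium.

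Larvae of D. simulans whose parents had been on octanoic acid had lower levels of 3 pigmentation genes. The gene e (ebony), which encodes the enzyme that joins dopamine to beta-alanine, stood at 162.1 ± 207 FPKM after octanoic acid and 685.9 ± 344 after standard medium (n = 6 each; -4.27, adjusted p = 0.0435), with 1.62 to 516 against 265.3 to 1097 per library. The tyrosine hydroxylase gene ple had 238.7 ± 288 and 1037 ± 655 FPKM (-3.88, 0.0435), and b (black), which acts in beta-alanine synthesis, had 67.05 ± 67.6 and 296.1 ± 157.5 (-2.70, adjusted p = 0.034). These are the 3 of 10 dopamine and melanin genes that fell, and 7 fell and 1 rose adjusted over the list alone. The drosomycin-like gene Drsl5 (-4.25) and the mucin-related gene Mur29B (-1.61) fell as well. Of 58 cuticle protein genes 2 rose, Cpr49Ah (1.60) and Cpr65Ax2 (1.63), and 5 adjusted over the list alone. Another 1 of the 4 genes that rose, bug (3.43), was listed at 0 in 5 of 6 libraries after standard medium and in 1 of 6 after octanoic acid. Ecdysone genes had a median of -0.66, with 5 of 13 down adjusted over the list alone. Complex I genes had a median of 0.41, muscle genes 0.75 and digestive genes 0.80, with 0 members past the test and, adjusted over the list alone, 1 for complex I. Camera adjusted p was 2.79e-11 for cuticle and for complex I, 1.32e-05 for muscle, 1.67e-05 for digestive, 8.68e-05 for ecdysone and 0.000365 for dopamine and melanin genes. None held: adjusted p = 0.0741, 0.0583, 0.084, 0.203, 0.203 and 0.203 with an estimated correlation, in that order.

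The D. simulans larval call was 21 genes, 4 higher and 17 lower, with a median of -0.13 over all genes and 991 at an unadjusted p under 0.05 against 358 expected. It was 57 with median-ratio rescaling, 10 with a pseudocount of 0.1 and 1 with D. simulans libraries alone (1727 unadjusted), where e, ple and b had adjusted p = 0.12, 0.121 and 0.118. With the pseudocount of 0.1 the calls of e and ple (0.0589 each), Drsl5 (0.0649), Cpr65Ax2 (0.0807) and Cpr49Ah (0.136) were lost, as were those of Drsl5 without the filter (0.0518) and Cpr65Ax2 without the trend (0.0525). Weights per genotype gave 503 genes. Single libraries decide it. The count was 0 without SO replicate 1, SO replicate 3 or OS replicate 1, 1 without SS replicate 1, 2 without SS replicate 3, OS replicate 3 or OO replicate 1, and 4 without SS replicate 2. It was 14 without OO replicate 3, 93 without OS replicate 2 and 259 without OO replicate 2. The calls of e, ple, Drsl5, Cpr49Ah and Cpr65Ax2 were each lost without any 1 of 9 libraries, and those of b, Mur29B and bug without any 1 of 8, with adjusted p for e up to 0.24 without OS replicate 1.

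Octanoic acid in the previous generation called 1 gene in D. sechellia larvae, CG13227, at 31.9 ± 9.25 FPKM after it and 12.7 ± 3.91 after standard medium (n = 6 each; 1.28, adjusted p = 0.0473). It was lost without each of 11 of the 12 libraries, OO replicate 3 being the exception, with adjusted p up to 0.358. With D. sechellia larvae alone the 1 call was Jon99Cii, at 2.26 ± 0.548 FPKM after octanoic acid and 10.25 ± 2.51 after standard medium (-1.77, adjusted p = 0.00286). In hybrid larvae 48 genes passed, among them the poly(A)-binding gene Pabp2 (3.075 ± 2.165 and 10.1 ± 3.785 FPKM; -1.54, adjusted p = 0.00129) and the sterol-binding gene Npc2g (-2.34, adjusted p = 0.0186). Antimicrobial peptide genes had a median of -0.59 there (1 of 22 down, 5 adjusted over the list alone; camera adjusted p = 0.0236), and adjusted p = 0.926 with an estimated correlation. With hybrid libraries alone 3 genes passed (203 unadjusted), and Pabp2 and Npc2g had an adjusted p of 1.0. The hybrid count was 158 without OS replicate 3, 143 without SO replicate 1 or 2, 81 without OO replicate 2 and 74 without SS replicate 2.

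**Figure D4:**
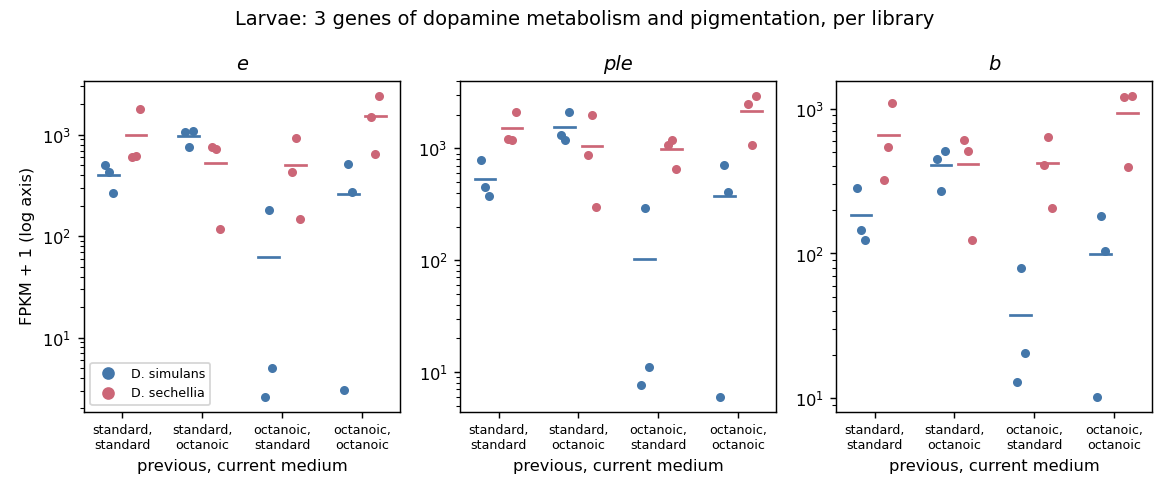
FPKM + 1 (y axis, log scale) of e, ple and b in each larval library of both species, by previous and current medium (x axis). Points are libraries and bars are means of 3; for e the 6 D. simulans libraries after octanoic acid span 1.62 to 516 FPKM and the 6 after standard medium 265.3 to 1097.

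Tests of the difference between groups named few genes. Jon99Cii responded to the previous medium differently in the 2 species as adults (-1.39, adjusted p = 0.0106), with 585 ± 61.8 and 614.9 ± 93.5 FPKM in D. simulans after octanoic acid and standard medium (n = 6 each). That call was lost without D. sechellia OS replicate 1 or 3 (adjusted p = 0.0673 and 0.0679), and there the count fell from 2 to 0. CG34312 was the other call for the previous medium (1.14, adjusted p = 0.00267) and the only call for the current medium by species (-1.14, adjusted p = 0.00267) and for current by previous medium in adults (-0.93, adjusted p = 0.00283). It left the tested genes without D. sechellia OS replicate 1, 2 or 3, and the count for the current medium by species was then 0. With a pseudocount of 0.1 the species differences of CG34312 were not called (adjusted p = 0.799 and 0.399). In larvae limma called 0 genes for species by current medium (28 unadjusted) and 0 for species by previous medium (553 unadjusted), and 1 for each with parental libraries alone. The species-by-previous count was 1 without D. simulans SO replicate 3, D. simulans OO replicate 2 or D. sechellia SO replicate 1. Lists differed there, beside a median of 0.26 for all genes: cuticle (median -0.79), complex I (-0.49) and glutathione transferase genes (-0.36) responded lower in D. sechellia than in D. simulans, with 1 member each past the test adjusted over the list alone. Camera adjusted p was 3.31e-14, 5.45e-12 and 1.7e-05, and adjusted p = 0.032 with an estimated correlation for all 3. These differences contain the shift of D. simulans larvae, whose calls single libraries decide. Egg and ovary genes differed in adults by -0.82 for the previous medium (1.42e-12) and 0.80 for the current medium (6.55e-12), and adjusted p = 0.0868 and 0.298 with an estimated correlation, and both contain D. sechellia OS replicate 1. With fry the adjusted p for the current medium was 0.978. For current by previous medium in larvae CG42488 (2.07, adjusted p = 4.34e-07) and CG42339 (-2.49, adjusted p = 0.000175) were called. Both calls rest on the hybrids. In hybrid larvae CG42488 was listed at 26.3 to 35.8 FPKM in the 3 SS libraries and at 0 in the other 9, and CG42339 at 0.251 to 0.616 in SS and at 69.6 to 215 in the other 9. In D. simulans larvae CG42488 was listed at 0 throughout, and in D. sechellia larvae at 7.73 to 24.3. The count was 1 in adults and went to 0 without D. sechellia OS replicate 1 or 2, and to 2 without D. sechellia OO replicate 2. Without single hybrid libraries it went to 6 (SS replicate 1, OO replicate 2), 5 (SS replicate 2, OS replicate 1), 2 (SS replicate 3), 3 (SO replicate 3, OS replicate 2), 7 (OO replicate 1) and 4 (OO replicate 3). In larvae the count of 2 went to 4 without hybrid SS replicate 2 and to 5 without hybrid SO replicate 2 or OS replicate 2. With weights per genotype CG42339 had an adjusted p of 0.0581.

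In hybrid adults the summed allele values of most muscle and ribosomal protein genes were below the mean of the parents. The myosin genes Mhc (25.3 ± 11.5 FPKM, against 445.9 ± 90.3 in D. simulans and 924.8 ± 417 in D. sechellia; n = 12 each) and Mlc2 were both lower by -4.64 (adjusted p = 3.2e-17 and 6.46e-19). Of 51 ribosomal protein genes 38 were lower and 13 higher, with a median of -1.34, and 8 of 11 muscle genes were lower and 2 higher. Median-ratio rescaling gave 42 lower and 6 higher, and 10 lower and 1 higher. RpL39 and RpL31 were listed at 0 in all 12 hybrid totals, and RpL27 and RpS27A in 11 of 12. Every cell uses these genes, so low hybrid totals are not read as less transcript. Among genes with at least 1 FPKM from each allele in 9 of 12 hybrid libraries, 28 of 39 ribosomal protein genes were lower and 11 higher, and 6 of 9 muscle genes lower and 2 higher, which leaves a partial loss of reads open. Higher than the mean of the parents were IM2 (33220 ± 17020 FPKM, 4.98), the larval cuticle gene Lcp65Ag3 (592.2 ± 181, 5.35), the rhomboid-like gene stet (5.31) and Bet5, a vesicle transport gene (5.11). This is a mean of log2 values, so a hybrid midway between unequal parents in FPKM also lies above it. Fatty acid oxidation genes were higher (19 of 21, 1 lower, median 0.74), and flipped with rescaling to 9 higher and 7 lower and a median of -0.08. Camera adjusted p was 6.36e-14 for ribosomal, 0.00324 for muscle and 0.00882 for fatty acid oxidation genes, and adjusted p = 0.0817, 0.768 and 0.748 with an estimated correlation. In all 4980 of 6420 genes differed, 3327 higher and 1653 lower with a median of 0.46, or 4868 rescaled, 2091 higher and 2777 lower with a median of -0.18.

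In hybrid larvae the summed allele values of Mhc, Mlc2 and most ribosomal protein genes were below the mean of the parents, with the same limit. Mhc was listed between 0 and 3.84 FPKM, at 0 in 5 of 12, against 157 ± 137 and 100.3 ± 96 in D. simulans and D. sechellia (n = 12 each; -5.83, adjusted p = 9.1e-12), and Mlc2 had -7.16. Of 10 muscle genes 7 were lower and 1 higher, and the list did not pass camera (adjusted p = 0.248). Of 52 ribosomal protein genes 39 were lower and 7 higher (median -2.07; camera adjusted p = 1.32e-12), and adjusted p = 0.845 with an estimated correlation. RpL39 was listed at 0 in 12 of 12 hybrid totals. Of 40 ribosomal protein genes with at least 1 FPKM from each allele in 9 of 12 libraries 30 were lower and 6 higher. DptA went the other way, at 20030 ± 6175 FPKM against 936.1 ± 486 in D. simulans and 14.7 ± 8.16 in D. sechellia (7.47, adjusted p = 3.39e-25). GNBP-like3 (6.66), IM2 (5.22) and OSCP1 (4.31) were also higher than the mean of the parents, which is a mean of log2 values. For OSCP1, at 1264 FPKM in D. simulans and 0.498 in D. sechellia, a hybrid midway in FPKM would also lie above it. In all 4818 of 7167 genes differed, 2082 higher and 2736 lower, and 5056 rescaled, 2082 and 2974. Of genes with a mean of at least 10 FPKM in both parents, 9 of 3651 in adults and 13 of 3557 in larvae were listed at 0 in all hybrid totals. The sources do not state how reads were assigned to the 2 alleles or what became of reads that fit both, so a 0 in hybrids is not read as absence of the transcript. Where each allele had at least 1 FPKM in 9 of 12 hybrid libraries, 3351 adult and 2495 larval genes differed. Of these 2774 were higher and 577 lower in adults, and 1538 higher and 957 lower in larvae. The filter acts on the hybrid values and drops genes that are low in hybrids, which favours higher values. The turn of the larval excess is thus not read as a result.

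Allelic ratios within hybrids address divergence in cis. In adults the D. sechellia allele of Fad2 stood at 604.8 ± 201 scaled FPKM and the D. simulans allele was listed at 0 in all 12 libraries (adjusted p = 1.25e-13), the same direction as between the species. Bet5 was also listed at 0 for the D. simulans allele. IM2 was higher from the D. sechellia allele (36000 ± 17480 against 3273 ± 1793; 3.51, adjusted p = 3.64e-12). The D. simulans allele was higher for epsilonTry (8880 ± 1748, the other allele listed at 0 in 8 of 12 and at most 69.6), as between the species. For OSCP1, IM4, RpL23A and RpL29 the D. sechellia allele was listed at 0 in all 12. An allele listed at 0 is not read as silent, since ribosomal protein genes are among them. In larvae DptA came from the D. simulans allele (75850 ± 29000 scaled FPKM, the other listed at 0 in 9 of 12), and GNBP-like3 from the D. sechellia allele (8624 ± 3297, the other listed at 0 in 8 of 12). Sgt, a co-chaperone gene, was higher from the D. sechellia allele (6.51). Complex I genes were higher from the D. sechellia allele in adults (14 of 20, 3 lower, median 0.41; camera adjusted p = 0.0119), and adjusted p = 0.0806 with an estimated correlation. Cuticle genes in larvae had 10 higher and 6 lower of 43, a median of -0.11 and a mean of 0.04, and camera called them higher than other genes (0.0458), and adjusted p = 0.356 with an estimated correlation.

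With each allele column scaled to its own total, 3089 of 6183 genes differed between alleles in adults, 1335 higher and 1754 lower for D. sechellia (median -0.11), and 3570 of 6994 in larvae, 894 and 2676 (median -0.47). The deposited D. sechellia allele columns held 79.9% to 88.7% of the summed FPKM of a hybrid adult and 64.4% to 74.2% of a hybrid larva. Scaled by the total of both alleles, 4645 adult genes differed, 4157 higher and 488 lower (median 1.99), and 3939 larval genes, 2403 and 1536. Against the own totals the sign changed for 2220 of 6049 adult genes (36.7%) and 1773 of 6950 larval genes (25.5%), and for 905 of 3068 and 380 of 3566 called ones. The single genes of the paragraph above kept theirs, and 19 of 77 called adult genes and 6 of 82 larval ones that met the rule for names changed sign. One allele was listed at 0 in all 12 libraries for 95 (D. simulans) and 55 (D. sechellia) adult genes whose other allele had a mean of at least 5. The larval numbers were 48 and 158. For the effect of the current medium on allelic ratios limma called 0 genes in adults (314 unadjusted, 309 expected) and 0 in larvae (492 unadjusted, 350 expected). The count was 1 in adults without OS replicate 1 or 3, and in larvae 2 without SO replicate 1 and 1 without SS replicate 2, SS replicate 3, OS replicate 1, OO replicate 1 or OO replicate 2.

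Differences between the parental and the allelic ratio address divergence in trans. In larvae 14 of 22 antimicrobial peptide genes had a higher D. sechellia to D. simulans ratio between parents than between alleles, and 1 a lower one, or 15 and 1 adjusted over the list alone (median 3.31; camera adjusted p = 4.69e-07, and adjusted p = 0.0405 with an estimated correlation). In adults 9 of 20 were higher and 0 lower (median 1.75; 0.00491), and adjusted p = 0.478 with an estimated correlation. Only 5 of the 22 larval and 6 of the 20 adult genes had at least 1 FPKM from each allele in 9 of 12 hybrid libraries, and of these 2 were higher and 1 lower in larvae, and 1 higher in adults. The list calls thus rest mainly on genes with low or unlisted alleles and are not read as divergence in trans. IM4 shows this: the parents had 8157 ± 3019 (D. sechellia) and 1478 ± 1199 (D. simulans) scaled FPKM in adults, and the alleles 0 in all 12 and 2732 ± 1182 (n = 12 each). RpL23A, a ribosomal gene also listed at 0 for 1 allele only, had 9845 ± 1586 and 3791 ± 329 in the parents. Sgt went the other way in adults, at 111.4 ± 20.2 and 171.7 ± 11.9 in the parents and 1037 ± 192 and 16.0 ± 9.99 for the alleles (-6.96, adjusted p = 2.45e-16). Digestive genes had 11 higher and 3 lower of 16 in adults, 12 and 3 adjusted over the list alone (0.0436), and proteasome genes 3 higher and 13 lower of 17 (0.0436), and adjusted p = 0.478 and 0.658 with an estimated correlation. With the shared total the digestive list flipped to 3 higher and 7 lower. Ribosomal protein genes in larvae had 22 higher and 12 lower of 52, 15 lower adjusted over the list alone (0.000937), flipped to 15 and 26 with the shared total, and adjusted p = 0.901 with an estimated correlation.

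In all 3634 of 6501 adult genes differed, 1470 higher and 2164 lower, and 2993 of 7283 larval genes, 1541 and 1452. Median-ratio rescaling gave 2245 higher and 1112 lower in adults and 2098 and 825 in larvae, and the shared total 569 and 4307, and 1016 and 3260. Where each allele had at least 1 FPKM in 9 of 12 hybrid libraries, 680 were higher and 1852 lower in adults, and 562 and 988 in larvae. This filter acts on allele values that enter the difference, and drops genes with an allele listed at 0 throughout. The turn to lower values in larvae is thus not read as a result. Of 6183 adult genes tested for both, 904 (14.6%) had an allelic difference only, 1315 (21.3%) a difference of ratios only and 2185 (35.3%) both, of which 1997 were of opposite sign. Of 6994 larval genes the numbers were 1596 (22.8%), 913 (13.1%) and 1974 (28.2%), with 1859 of opposite sign. With the shared total the adult numbers were 389, 457 and 4256 (70.3%) of 6051, with 4183 of opposite sign, and the larval ones 973, 1178 and 2966 (42.7%) of 6954, with 2864. The classes thus depend on the scale. The allelic ratio enters both terms, so errors in it favour opposite signs. Across genes, which are not independent replicates, parental and allelic ratios had r = 0.346 and rho = 0.242 in adults and r = 0.35 and rho = 0.331 in larvae. They had the same sign in 58.3% of adult and 69.4% of larval genes, in 59.7% and 63.5% with median-ratio rescaling and in 36% and 49.9% with the shared total.

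**Figure D5:**
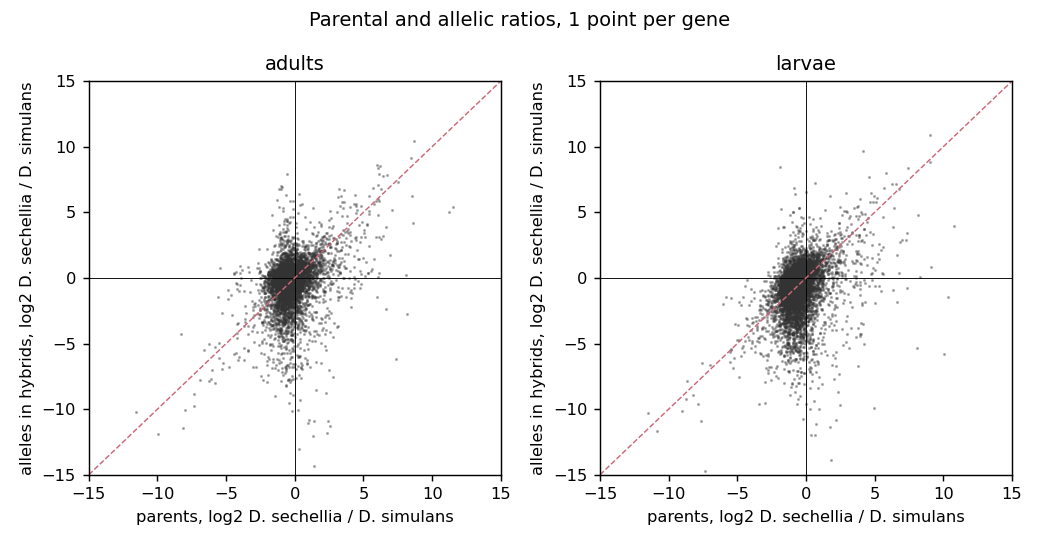
Log2 ratio of D. sechellia to D. simulans between parents (x axis) and between alleles in hybrids (y axis), each column scaled to its own total, with 1 point per gene (6183 in adults, 6994 in larvae). The dashed line marks equal ratios; across genes r is 0.346 in adults and 0.35 in larvae.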

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

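The tests of reads carried over between species and of each difference with weights per genotype were chosen only after the result was seen. Each result here is a difference between groups in a response, tested as an interaction. Jon99Cii responded to the previous medium differently in adults of the 2 species (-1.39). CG34312 differed between the species in its response to the current medium (-1.14) and to the previous medium (1.14), and its response to the current medium depended on the previous medium in adults (-0.93). In larvae the response to the current medium depended on the previous medium for CG42488 (2.07) and CG42339 (-2.49). CG34312 was listed above 1 FPKM in 3 adult libraries, all of D. sechellia OS, and the 2 larval genes took their pattern from the 3 hybrid SS libraries. Such a pattern within all 3 replicates of 1 group and no other cannot be assigned to the medium or to the handling of that group from these data. For CG34312, CG42488 and CG42339 no explanation was tested.

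The fall of Jon99Cii, epsilonTry and CG2233 in D. sechellia adults after octanoic acid concerns genes that are abundant in D. simulans (600.0 ± 77.2 FPKM for Jon99Cii) and low in D. sechellia (9.9 ± 5.92). Reads carried over from D. simulans libraries would raise all such genes together in the libraries after standard medium. The other 10 genes abundant in D. simulans and low in D. sechellia had a median of -0.09 (SD 0.38, range -0.49 to 0.75), short of the -1.45, -1.19 and -1.15 of the 3 genes. CG31948, CG13426, CG31041 and Jon44E averaged 0 to 0.909 FPKM in D. sechellia, too low to show such a fall on log2(FPKM + 1). RpS28a and OSCP1 may be missed by mapping in 1 genome. CG14893, CG32944, His1:CG33849 and mag, at 2.3 to 5.6 FPKM, had 0.75, 0.30, -0.18 and -0.23. These did not fall like the 3 genes, but they are few and low, so carry-over is not excluded. In D. sechellia larvae, where carry-over was not tested, Jon99Cii (-1.77), epsilonTry (-1.12), Jon44E (-0.89) and Jon65Aii (-0.52) were also lower after octanoic acid. Jon44E stood at 3.34 FPKM there and at 1002 in D. simulans larvae. None of them was called in the fit of all genotypes, RpS28a went the other way (0.43), and such genes were picked by small p. A response to the medium of the parents stays open as the biological explanation, and a difference in handling between the cohorts of parents could not be tested.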

How the results depend on the processing

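Weights per genotype, restricted gene sets, unscaled allele columns and median-ratio rescaling of variance shares were tests chosen only after the result was seen. Apart from leaving out libraries, 160 of the counts and shares stayed within the bounds set for them (1.5 times for counts, 1 SD for shares) and 55 moved; for named genes 762 calls were the same and 49 were no longer past the threshold. Leaving out 1 library at a time gave 519 and 93 for counts, and 2916 and 93 for genes. None of the gene results counted here changed direction, but some others among the called genes that met the rule for names changed sign. With the shared total these were 19 of 77 (allelic ratio) and 16 of 86 (difference of ratios) in adults and 6 of 82 and 4 of 76 in larvae. With median-ratio rescaling they were 5 of 86 (difference of ratios) and 1 of 87 (hybrids) in adults and 1 of 88 (species) in larvae. Where not stated, the cause was not tested.

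Median-ratio rescaling gave 57 genes for the previous medium in D. simulans larvae, 0 in D. sechellia larvae and 81 in hybrid larvae, 144 for the current medium in hybrid larvae, 1 for species by current medium in larvae, and variance shares of 49.6% for stage and 28.3% for genotype. No filter on low values gave, for the previous medium, 1 (D. simulans adults), 16 (D. sechellia adults) and 2 (D. sechellia larvae), and for the current medium 5 (D. sechellia adults), 2 (D. simulans larvae) and 1 (D. sechellia larvae). A pseudocount of 0.1 gave 0 and 1 in adults for species by current and by previous medium, 1 and 1 in larvae, 3 in adults and 5 in larvae for current by previous medium, 10 for the previous medium in D. simulans larvae, 113 for the current medium in hybrid larvae, and shares of 49.3% (stage), 25.3% (genotype) and 0.344% (current medium). limma without the mean-variance trend gave 0 for the previous medium in D. sechellia larvae. Only the libraries compared gave 0 for both media in D. sechellia and in hybrid adults, 1 for the previous medium in D. simulans larvae, 3 for each medium in hybrid larvae, and 1 each for species by current and by previous medium in larvae. The shared total gave 4645 for the allelic ratio in adults and the columns as deposited 4675, by construction of the scale. Weights per genotype gave, for the current medium, 1 (D. simulans adults), 10 (hybrid adults), 4 (D. simulans larvae) and 7 (hybrid larvae); for the previous medium, 1 (hybrid adults), 503 (D. simulans larvae), 2 (D. sechellia larvae) and 4 (hybrid larvae); in larvae, 1 and 6 for species by current and by previous medium; and 3 in adults and 1 in larvae for current by previous medium. Fewer genes were tested with rescaling and genes at 1 or more in 9 libraries of both species (2924 for species in adults), and with genes at 1 or more in both alleles of 9 hybrid libraries (in larvae 2495 for hybrids, 1847 for the allelic ratio and 1550 for the difference of ratios). With an estimated correlation 5 list calls held.

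The replicate block gave 10 for the previous medium in D. simulans larvae and 0 in D. sechellia larvae. In the former set the block left e and ple at an adjusted p of 0.0502 each, Drsl5 at 0.0535 and Cpr65Ax2 at 0.0597, and in the latter CG13227 at 0.059. Replicate numbers were not taken as pairs, since no label gives them a meaning and the lowest r of residuals with the same number was -0.07 or below in every set. D. simulans larvae came closest to pairs, with a mean r of 0.34 and 11 of 12 libraries that correlated best with their own number, as a hint from the data. The other sets had a mean r between -0.11 and 0.10. A replicate block was not possible for the allelic ratio, where replicates are nested in the library block. For stage, hybrids against parents, the difference of ratios and current by previous medium, the fit already holds only the libraries compared.

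Leaving out each library in turn gave these ranges, adults then larvae: species 4492 to 4628 and 3823 to 4084, hybrids 4918 to 5000 and 4723 to 4869, allelic ratio 2942 to 3035 and 3392 to 3507, difference of ratios 3505 to 3706 and 2819 to 3149, current medium on allelic ratios 0 to 1 and 0 to 2, current medium in D. simulans 0 to 1 and 1 to 3, D. sechellia 0 to 4 and 0 to 1, hybrids 294 to 690 and 51 to 464, previous medium in D. simulans 0 to 1 and 0 to 259, D. sechellia 3 to 24 and 0 to 1, hybrids 125 to 205 and 41 to 158, species by current medium 0 to 1 and 0 to 0, species by previous medium 0 to 3 and 0 to 1, current by previous medium 0 to 7 and 2 to 5. Stage ranged from 6241 to 6304. Without each replicate number the shares were 46.0% to 48.3% (stage), 29.8% to 30.8% (genotype), 0.373% to 0.461% (current medium) and 0.313% to 0.556% (previous medium). Depth is unknown, and the differing floors of the columns limit what a 0 shows.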

Other observations

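The tests of male larvae and of reads shared between paralogs were chosen only after the result was seen. Larval libraries carried transcripts of spermatogenesis. The testis regulator sa stood at 4.79 ± 1.71 FPKM in D. simulans larvae and 4.42 ± 1.91 in D. sechellia larvae (n = 12 each), and aly at 1.77 ± 0.744 and 2.3 ± 0.825. The testis proteasome genes Prosbeta5R2 (7.9 to 61.8 FPKM), Prosalpha6T (7.56 to 36.8) and Prosbeta4R1 (5.19 to 29.7) were present in all 24 parental larval libraries and listed at 0 in all 24 parental adult libraries. In hybrid larvae dj stood at 34.6 ± 20.3 FPKM and Mst98Cb between 0 and 10.2.

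Of 5 tested genes counted as testis genes in the fixed male list, 1, Est-6, is not specific to the testis. It had at least 1 FPKM in all 24 parental adult libraries, as adult tissues also express it. In all 24 parental larval libraries 3 of the 5 had at least 1 FPKM (dj, Mst98Cb and sa). This is consistent with male larvae among the pooled animals in each library, since the larvae are described as female. Reads shared with paralogs that adults also express would give the same genes values in adults, whereas their median adult minus larval difference was -5.56. This argues only against paralogs expressed in adults, and paralogs expressed mainly in larvae are not excluded. The low adult values of dj and Mst98Cb were known when the test was chosen, so it restates them. Apart from the sex of the pooled larvae, no biological explanation was tested.

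In D. simulans larvae the shift with the previous medium, lower e, ple and b and 2 higher cuticle genes, was set against larvae of different ages within the third instar. Across 6879 genes, which are not independent replicates, its log2 differences had |r| = 0.412 with the first component of the differences between replicates of D. sechellia larvae, a component that holds 44.7% of their variance, but a rank correlation of 0.0217. The r leaves a difference in age open, but no label ties the component to age, and other differences between replicates could lie behind it. The rank correlation near 0 shows that the match does not extend over genes at large. Cuticle genes lay at a median loading rank of 92.7%, muscle genes at 97.0% and dopamine and melanin genes at 10.6%, while complex I genes lay at 48.3%. Ecdysone genes, whose median fell in the shift, lay at 64.8%, nearer the rank of cuticle genes than that of dopamine and melanin genes. A response to the medium of the parents stays open beside a difference in age, since age was not recorded.

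Other splits of the same libraries into groups of the same sizes were counted, 100 for each result with the real one included. As many genes as in the real split were called in 1 of 100 for stage (real 6287, highest other 2324), and, in adults and larvae, in 1 and 1 for species (4632, highest other 3514; 3998, 2114), 1 and 1 for hybrids against parents (4980, 2307; 4818, 874), 1 and 1 for the allelic ratio (3089, 3; 3570, 1437), and 1 and 1 for the difference of ratios (3634, 1206; 2993, 859). Chance can be excluded for these. The share was also under 5 in 100 for the current medium in hybrid adults (3 of 100; 432, 658) and the previous medium in D. simulans larvae (4 of 100; 21, 136). No effect of the medium is read from either. The first had 0 genes with hybrid libraries alone and 175 false calls in simulated hybrids without any change, and the second went to 0 without any 1 of 3 libraries.

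Chance could not be excluded for other results with a real count above 0. For the current medium the number of splits was 58 in D. sechellia adults (real 1, highest other 536), 42 in D. simulans larvae (1, 49) and 49 in hybrid larvae (68, 1779). For the previous medium it was 17 in D. sechellia adults (5, 764), 84 in hybrid adults (109, 550), 22 in D. sechellia larvae (1, 34) and 62 in hybrid larvae (48, 1908). In adults it was 22 for species by current medium (1, 8) and 7 for species by previous medium (2, 28), and for current by previous medium it was 56 in adults (1, 132) and 18 in larvae (2, 17). Where the real count is 0 all 100 splits give as many by construction, so they say nothing about chance. This holds for the current medium in D. simulans adults (highest other 3) and D. sechellia larvae (31), the previous medium in D. simulans adults (2), species by current (3) and by previous medium (8) in larvae, and the current medium on allelic ratios in adults (2) and larvae (4). Some splits called several times the real count in D. sechellia adults, hybrid larvae, D. simulans larvae and, for the previous medium, hybrid adults. What lies behind such splits was not tested. In simulated hybrids without any change the fit of all genotypes gave 175 (adults) and 165 (larvae) false calls for the current medium.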
